A study of Phalaenopsis amabilis with 15 samples.

How the data were processed

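RNA was sequenced from the uppermost young leaves of Phalaenopsis in 15 libraries, 3 for each of 5 groups, and each library pooled 3 plants. The experiment used 120 plants, shared between the long and the short photoperiod. Before treatment they stood in 12 h of light at 28 °C by day and 25 °C by night and 70% humidity. The hour of harvest is not given, and neither are sequencing batches or dates. The labels call the plants P. amabilis, while the deposited table lists loci of P. equestris on genome scaffolds and a chloroplast record. Reads of one species were thus counted on loci of another, and no reference genome was used here. The genome build and the strand setting are not stated.

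The authors deposited one table of 21144 loci with read counts, FPKM values and protein matches. Per the file headers, the values used here are read counts per gene, which are whole numbers with a different total in each library. The authors also gave FPKM, which follow the read count divided by gene length and by the sum of counts in the table. Gene length in bases and start and end positions, other columns of the deposited table, were used to test that formula and to place genes. The formula held within 0.01 reads for 21143 genes in every library and failed for 1 gene, SOC1, in 6 libraries. The FPKM values served for that check alone. The submitters' notes name cutadapt 1.15, HISAT2 2.0.5, HTSeq 0.9.1 and DESeq 1.30.0, without saying what each did.

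For replicates 1, 2 and 3, library totals were 12892377, 13143196 and 13436777 counts in the control. They were 13740272, 13531682 and 13482173 in LD_20d and 12992442, 11246777 and 12907648 in SD_20d. They were 13916937, 11836889 and 14225626 in LD_40d and 13663222, 11748364 and 14637388 in SD_40d. Loci on the chloroplast record (46 in the table) took 0.000916% to 0.00299% of counts. Counting intervals and floors cover counting error alone, since PCR copies are not independent molecules. A fold against a group with no count is given as a lower bound, with a floor of 3 counts over the group, and with 1 to 3 counts as a ratio with its counting interval.

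Genes were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling) in one fit to all 15 libraries with a mean per group and no covariate. The expression filter of edgeR kept 16700 genes. P-values were adjusted by Benjamini-Hochberg over these genes, and a call is an adjusted p under 0.05. Standard errors are the size of the log2 fold change over the root of F. The 9 comparisons were SD against LD at 20 and at 40 days, each treated group against the control, 40 against 20 days within each photoperiod, and the photoperiod by time interaction. These tests, the gene lists and the choice of genes to name were set before the data were examined. CPM are scaled by TMM.

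Gene groups were tested as 30 fixed lists, with members found by words in the gene descriptions, which 20054 genes have (16334 from Swiss-Prot). The lists covered the circadian clock, light signalling, flowering time, SPL and AP2 factors, floral organ MADS genes, gibberellin, auxin, cytokinin, abscisic acid, ethylene, jasmonate, light harvesting, photosystem subunits, chlorophyll synthesis, the Calvin cycle, CAM, and sugars and starch. Further lists were cold and dehydration, heat shock, flavonoids, defence, antioxidants, cell cycle and histones, cell wall, cytosolic ribosome, cuticle and epidermis, vascular tissue, meristem, guard cells, and retroelements and viruses. A gene could be in several lists. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 between genes and, beside it, an estimated one. Counts of members are given over all genes tested and adjusted over the list alone. Lists for the cell cycle, meristem, guard cells, vascular tissue, epidermis, floral organs and retroelements also stand for other tissue or RNA that a leaf sample can hold.

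Annotation terms came from the GO and pathway columns of the table (10380 and 5192 genes). Terms of 10 to 500 tested genes were tested with a one-sided Fisher's exact test, rises and falls apart, against tested genes that carry a term of that kind. The overlap of calls used Fisher's exact test, two-sided, and for the shared controls 20 simulations of unchanged groups. Genes to name were the 6 steepest rises and 6 steepest falls between photoperiods, and 4 of each elsewhere, among calls with a mean log2 CPM of 2 or more, groups that did not overlap and an informative description. To these came the called members of each list with the smallest adjusted p (2 between photoperiods, 1 elsewhere). With fewer than 12 calls, the 12 smallest p-values were named. Clock and flowering-time genes with a mean log2 CPM of 1 or more and each PEPC gene were reported whatever their test, as counts with examples. SOC1 falls under these rules as a flowering-time gene, while its separate treatment for its FPKM was chosen after its values were seen.

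The calls were tested on simulated data at the size and spread of this design, with 200 of 16700 genes changed. The changed genes were drawn among those above a floor of mean CPM, and each gene was drawn independently. Differences that many genes of a library share were thus not simulated, and the rates that follow do not cover them. At 20 days 50% of 100 genes changed 2-fold and 93% of 100 changed 4-fold were recovered, with 6 false calls among 149. At 40 days it was 52% and 90%, with 2 false calls among 144. Replicate numbers did not pair the libraries as a whole. Of 30 pairs with the same number in different groups, 9 had deviations from their group means that correlated across genes at over 0.1. The mean of the 30 was -0.00100. Between SD and LD, pairs with the same number correlated at 0.364, 0.251 and 0.0719 at 20 days. At 40 days these values were -0.212, 0.192 and -0.257, so a pairing at 20 days is left open. The replicate number as a block was therefore tried as an alternative alone.

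Alternatives planned before the data were examined were DESeq2 1.42.0, limma-voom, DESeq2 size factors, upper-quartile scaling, no filter, a filter at a CPM of 1 in 3 libraries, a fit to the groups compared alone, a log2 change of at least 1, the replicate block, an estimated correlation for the lists, and leaving out each library in turn. Chosen after seeing the data were robust dispersions, lists without members that share a name by chance, SOC1 counts exchanged between groups, annotation terms for 40 against 20 days, fits for AGL65 with a library left out, and recovery in simulation by count. Changes of pseudocount or of a filter on normalised values were planned for a table without counts and were not run. Raw reads were not analysed here.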

Results

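Gene expression was measured by RNA sequencing in the uppermost young leaves of Phalaenopsis amabilis, a moth orchid, in 5 groups of 3 libraries, each library pooled from 3 plants. The control group was taken at day 0 from plants kept in 12 h of light at 28 °C by day and 25 °C by night. The other 4 groups were taken after 20 or 40 days at 25 °C by day and 18 °C by night, under a long photoperiod of 16 h light (LD) or a short photoperiod of 8 h light (SD). Library totals ran from 11246777 to 14637388 counts over 21144 genes, and 1689 genes had no count in any library. On the plot of principal components, the first axis (44.6% of the variance) ran from the 20-day to the 40-day libraries and the second (24.0%) parted the 3 control libraries from the other 12. The SD_40d libraries were spread along the first axis, with replicate 1 at -16.9 and replicates 2 and 3 at -77.6 and -89.3. Gene values below are log2 fold changes ± standard error from a fit to all 15 libraries, or CPM (counts scaled to a common library size) ± SD, with n = 3 libraries per group. Gene names are the best protein matches that the table lists for each locus of the related species P. equestris, and positions are on its scaffolds.

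**Figure D1:**
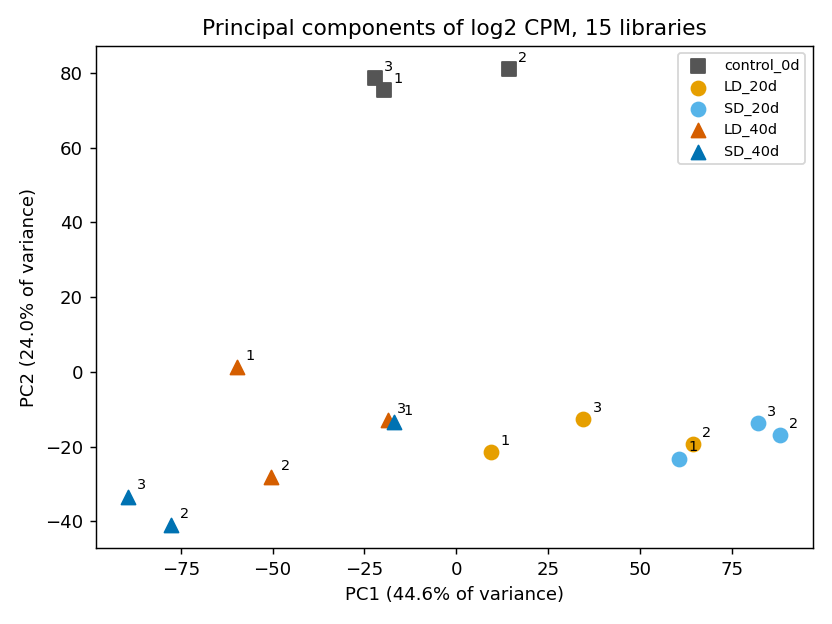
Scores of the 15 libraries on the first 2 principal components of log2 CPM, numbered by replicate, with colour and symbol for the group. The control libraries sit apart from the others on the second axis, and the 20-day libraries (9.5 to 88.1) lie above the 40-day libraries (-89.3 to -16.9) on the first.

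The series asks how photoperiod relates to floral induction, and the direct test is SD against LD at equal age and temperature. At 20 days, leaves under SD held less transcript of several clock-related and flowering-time regulators than leaves under LD. RVE7 (LOC110021130, scaffold NW_018164564.1, 9317 to 12770), a Myb-like factor related to the clock gene LHY, fell by 3.39 ± 0.40 (adjusted p = 0.00292), from 209 ± 40.5 to 19.9 ± 4.48 CPM. Its relative RVE1 (LOC110020906, scaffold NW_018164551.1, 66501 to 70183) fell by 1.87 ± 0.18 (adjusted p = 8.8e-04). COL9 (LOC110027028, scaffold NW_018164852.1, 690072 to 710632), a zinc finger protein of the CONSTANS-like family, fell by 2.57 ± 0.24 (adjusted p = 8.8e-04), from 72.6 ± 13.4 to 12.2 ± 1.42 CPM. PPCK1 (LOC110038259, scaffold NW_018250288.1, 8439 to 9699), the kinase that activates the carbon-fixing enzyme PEP carboxylase (PEPC) in crassulacean acid metabolism (CAM), fell by 6.21 ± 0.81 (adjusted p = 0.00493), from 656 ± 207 to 8.87 ± 3.15 CPM. Of 19 genes of light-harvesting proteins, which bind chlorophyll in the photosystem antennae, 4 rose under SD and 1 fell.

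The lists were made by words, so 3 of the 29 genes counted as clock genes and 4 of the 43 counted as flowering-time genes only share letters with one. They include YUCCA10, tRNA nucleotidyltransferases and EH domain proteins, and 0 of these 7 were called between photoperiods. Of 43 flowering-time genes tested, 5 fell and 0 rose at 20 days (0 up and 9 down when adjusted over the list alone). Besides COL9, these were the CDF2 loci LOC110037410 (-1.67 ± 0.23) and LOC110019467 (-1.64 ± 0.26), Dof factors known as repressors of CONSTANS, COL10 (LOC110038787, -1.02 ± 0.19) and COL14 (LOC110023156, -1.11 ± 0.18), with adjusted p from 0.00534 to 0.0264. The CDF2 locus with the highest counts, LOC110026496, differed by -0.90 ± 0.22 and was not called (adjusted p = 0.0706). The median of this list was 0.13, its mean was -0.18, and its test did not pass (adjusted p = 0.349). Of 29 clock genes, 2 fell (RVE7 and RVE1) and 27 were not called (2 up and 6 down when adjusted over the list alone). GIGANTEA (GI, LOC110019219), an evening clock component, differed by -1.10 ± 0.33 (adjusted p = 0.122). The LHY loci LOC110025280 and LOC110023014 differed by -0.02 ± 0.30 and 0.36 ± 0.12 (adjusted p = 0.985 and 0.16). The hour of harvest is not given, so a change of level and a change of daily timing cannot be separated for clock genes. The same holds at both ages for any other gene named here whose transcript cycles over the day, which was not tested. GHD7-like LOC110024148, related to a rice repressor of flowering, differed by -1.66 ± 0.37 (adjusted p = 0.0532). Of 38 light signalling genes, 4 fell and 0 rose (0 up and 7 down when adjusted over the list alone). HYH (LOC110030608, -2.79 ± 0.50) and HY5 (LOC110032590, -1.05 ± 0.18), factors that promote light responses, and SPA3 (LOC110029638, -1.02 ± 0.18), a partner of the COP1 ubiquitin ligase, were among them (adjusted p = 0.018 to 0.0248).

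Of 19 light-harvesting genes, 4 rose and 1 fell under SD at 20 days (9 up and 3 down when adjusted over the list alone). LHCB3 (LOC110019911, 1.91 ± 0.37), CAB37 (LOC110031670, 1.27 ± 0.20), CAB8 (LOC110023588, 1.26 ± 0.18) and LHCA4 (LOC110028982, 1.09 ± 0.20) rose (adjusted p = 0.00633 to 0.0318). POR1 (LOC110033798, 0.96 ± 0.15), the light-dependent enzyme of chlorophyll synthesis, rose as well (adjusted p = 0.011). PSBS (LOC110028411), which protects photosystem II in excess light, fell by 1.25 ± 0.20 (adjusted p = 0.0155). In carbon metabolism, the chloroplast starch-degrading enzymes BAM3 (LOC110020311, -3.57 ± 0.45) and AMY3 (LOC110033066, -1.35 ± 0.19) fell (adjusted p = 0.00493 and 0.00657). So did transketolase (LOC110028778, -1.05 ± 0.22) and phosphoglycolate phosphatase (PGLP1A, LOC110027215, -0.92 ± 0.18) of the Calvin cycle and photorespiration (adjusted p = 0.043 and 0.0351). The PEPC loci LOC110022615 (-0.12 ± 0.12) and LOC110027447 (-1.18 ± 0.64) did not pass (adjusted p = 0.67 and 0.374). GA2OX8 (LOC110022722), which inactivates gibberellins, had no count in SD_20d and was at least 78.8-fold lower there than in LD_20d, with a floor of 3 counts over the group (adjusted p = 0.017). The phosphatase PP2C06 (LOC110022579, -1.17 ± 0.14) of abscisic acid signalling, the hydrolase HL3 (LOC110032093, -2.96 ± 0.40), HSFC1 (LOC110029688, -1.96 ± 0.35), a heat stress transcription factor, and COR27 (LOC110028958, -0.83 ± 0.18), a cold-regulated protein, also fell (adjusted p = 0.00292 to 0.0491). The mitotic kinase AUR3 (LOC110030091, 1.26 ± 0.23) and the cytokinin response regulator ORR10 (LOC110034179, 1.12 ± 0.21) rose (adjusted p = 0.0256 and 0.0264).

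As whole lists at 20 days, 11 were called, and none of these calls held with an estimated correlation (adjusted p = 0.45 to 0.572 with an estimated correlation). Light-harvesting (median 0.39, adjusted p = 0.016), cell cycle and histone (median 0.37, adjusted p = 8.8e-10) and cytosolic ribosome genes (median 0.20, adjusted p = 3.7e-09) passed upward under SD. The lists for the clock (median -0.17, adjusted p = 0.0354), light signalling (median -0.04, adjusted p = 0.0354), photosystem subunits (median -0.16, adjusted p = 0.00489), the Calvin cycle (median -0.43, adjusted p = 4.7e-04) and CAM (median -0.16, adjusted p = 0.0141) passed downward. So did those for sugars and starch (median -0.08, adjusted p = 0.0351), flavonoids (median -0.26, adjusted p = 0.0364) and meristem markers (median -0.37, adjusted p = 0.0351). Without 11 ferredoxin-dependent enzymes of other pathways, the photosystem list did not pass (adjusted p = 0.0825). Cell cycle scores, in mean centred log2 CPM, were 0.68 to 1.05 in SD_20d and -0.20 to 0.84 in LD_20d, so the share of dividing tissue marker transcripts moved with the groups compared. Among annotation terms, antenna proteins were over-represented among the rises (4 of 13 genes, adjusted p = 1.2e-05). In all, 144 of 16700 genes were called (28 up, 116 down, so 19.4% up). The share of rises was 34.2% with limma-voom, 26.2% with DESeq2, 12.5%, 39.1% and 7.41% without LD_20d replicates 1, 2 and 3, and 13.9%, 12.5% and 0% without SD_20d replicates 1, 2 and 3. The count was 825 with DESeq2 and 78 with a log2 change of at least 1, and it was 24, 892 and 27 without LD_20d replicates 1, 2 and 3, 16 without SD_20d replicate 2 and 5 without SD_20d replicate 3. Of 28 called genes named here, 4 (RVE1, RVE7, COL9 and PP2C06) kept their call whichever library was left out, and 24 did not; without LD_20d replicate 1, 6 lists passed.

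**Figure D2:**
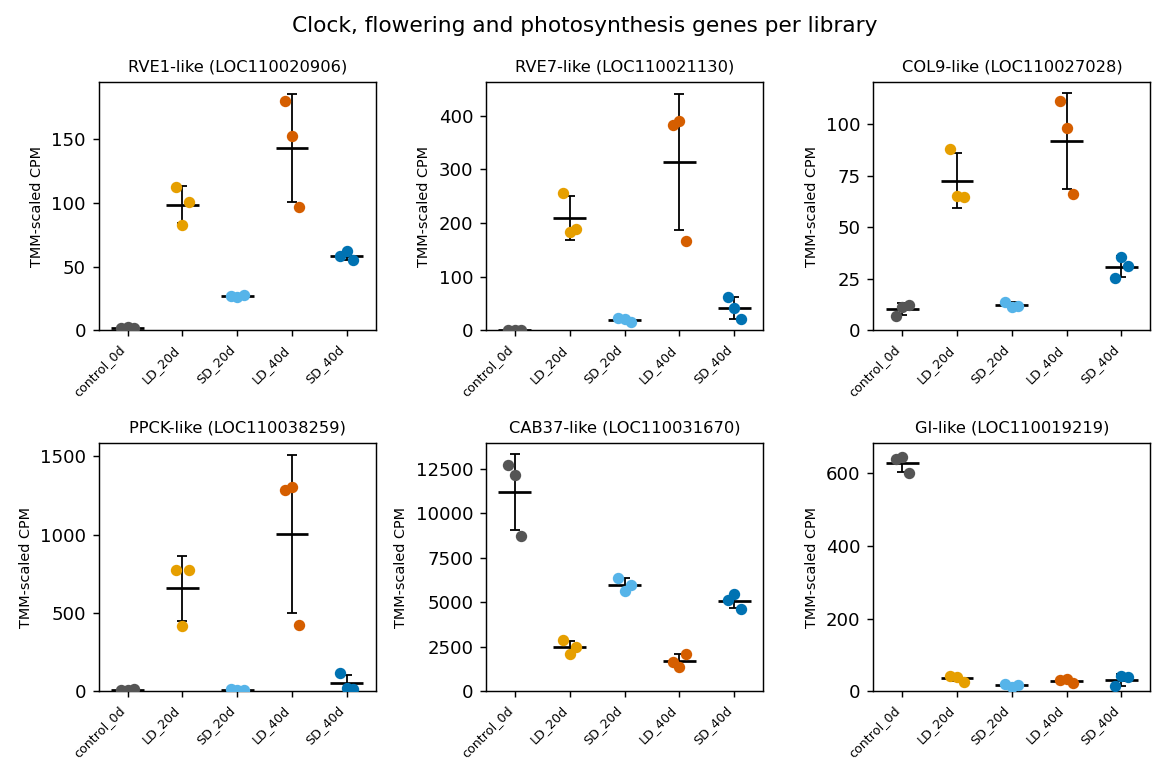
TMM-scaled CPM of 6 named genes in each library (points, 3 per group), with the group mean (line) and SD (bar), on linear axes that start at 0. RVE1, RVE7, COL9 and PPCK are lower in SD than in LD at both ages, CAB37 is higher, and GI is far lower in the 12 treated libraries than in the 3 control libraries; the panels were picked after the values were seen.

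At 40 days the same test found several of these differences again. RVE7 fell by 2.91 ± 0.39 under SD, RVE1 by 1.29 ± 0.18 and COL9 by 1.57 ± 0.23 (adjusted p = 0.0147 to 0.0153). PPCK1 LOC110038259 fell by 4.32 ± 0.73 (adjusted p = 0.0276), from 1004 ± 504 to 50.1 ± 55.5 CPM, and GA2OX8 by 4.74 ± 0.82 (adjusted p = 0.0299). CAB37 (1.58 ± 0.21), CAB8 (1.22 ± 0.18) and POR1 (1.02 ± 0.15) rose (adjusted p = 0.0147 for each). PIL13 (LOC110028745), a phytochrome-interacting factor that acts in light signalling, rose by 2.0 ± 0.33 (adjusted p = 0.0272), from 280 ± 18.0 to 1117 ± 453 CPM.

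Among calls with a mean log2 CPM of 2 or more, groups that did not overlap and an informative description, the steepest rises at 40 days were the BT1 loci LOC110022335 (5.92 ± 1.07) and LOC110022349 (5.11 ± 0.90), proteins with BTB/POZ and TAZ domains. They were followed by GATA7 (LOC110027045, 3.0 ± 0.53), a transcription factor, and the enzyme that sets fructose 2,6-bisphosphate, FKFBP (LOC110028324, 2.08 ± 0.36), with adjusted p from 0.0295 to 0.0297. The steepest falls by the same rule, besides those above, were the kinase CIPK11 (LOC110033924, -3.03 ± 0.60), NIN1 (LOC110037681, -2.14 ± 0.39), an invertase that splits sucrose, and CYP93G1 (LOC110019181, -2.13 ± 0.25), a cytochrome P450 (adjusted p = 0.0144 to 0.0455). The abscisic acid list held a rise of NCED1 (LOC110033126, 1.10 ± 0.19) and a fall of PP2C06 (-0.68 ± 0.14), with adjusted p = 0.0276 and 0.0471. The Swiss-Prot match of LOC110033126 is NCED1, an enzyme of abscisic acid synthesis, but its other protein description is a zeaxanthin cleavage dioxygenase. A role of this locus in the synthesis of that hormone is therefore uncertain. The auxin importer LAX2 (LOC110022504, 1.36 ± 0.22) and RFS6 (LOC110039017, 1.09 ± 0.20), annotated in raffinose synthesis, rose, while phosphofructokinase PFK3 (LOC110029954, -1.06 ± 0.17) and the chloroplast chaperone ATJ8 (LOC110019337, -1.26 ± 0.24) fell (adjusted p = 0.0234 to 0.0359).

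Clock genes at 40 days numbered 2 down, 0 up and 27 not called (4 up and 4 down when adjusted over the list alone). Flowering-time genes numbered 1 up (SOC1) and 1 down (COL9) of 43 (4 up and 8 down when adjusted over the list alone). PRR95 (LOC110033028) differed by 2.31 ± 0.63, LHY LOC110025280 by 0.95 ± 0.30, GI by 0.09 ± 0.33 and GHD7-like LOC110024148 by 1.0 ± 0.33, and none of them passed (adjusted p = 0.119 to 0.92). The CDF2 loci LOC110019467 (-0.88 ± 0.25), LOC110037410 (-0.75 ± 0.22) and LOC110026496 (0.38 ± 0.21) and COL10 (-0.92 ± 0.19) did not pass either (adjusted p = 0.0537 to 0.425). PEPC loci LOC110022615 and LOC110027447 differed by -0.07 ± 0.12 and 0.75 ± 0.64 (adjusted p = 0.812 and 0.611). As lists, 3 were called, and none of them held with an estimated correlation (adjusted p = 0.956 with an estimated correlation for each). Light-harvesting genes passed upward (median 0.55, adjusted p = 0.0182), with 3 up and 1 down of 19 (10 up and 5 down when adjusted over the list alone). Heat shock and chaperone genes passed upward (median 0.17, adjusted p = 2.1e-04) with 0 up and 1 down of 154 over all genes and 21 up and 3 down when adjusted over the list alone, and cell cycle genes passed downward (median -0.23, adjusted p = 0.0238). Heat shock scores were 0.71 and 0.50 in SD_40d replicates 2 and 3 and -0.21 in replicate 1, against -0.14 to 0.05 in LD_40d. Circadian rhythm was over-represented among the falls (5 of 88 genes, adjusted p = 0.0238).

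In all, 77 genes were called at 40 days (27 up, 50 down, so 35.1% up). The share of rises was 48.7% with DESeq2, 27.3% with limma-voom, 10.5% and 29.1% without LD_40d replicates 2 and 3, and 41.7% and 33.3% without SD_40d replicates 1 and 3. The count was 614 with DESeq2, 45 with replicate number as a block and 0 in a fit to these 6 libraries alone by edgeR (where 1614 genes had an unadjusted p under 0.05). It was 0 (2020 at an unadjusted p under 0.05), 19 and 127 without LD_40d replicates 1, 2 and 3. It was 2025 (with all 77 among them), 0 (1582 unadjusted) and 6 without SD_40d replicates 1, 2 and 3. Each of the 23 called genes named here lost its call in at least 1 of these fits, and 6 lists passed without LD_40d replicate 2.

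SOC1 (LOC110020085, scaffold NW_018164532.1, 122255 to 163966), a MADS-box factor that promotes flowering, has to be read apart. Its CPM as deposited were 20.6 ± 4.16 in the control, 53.2 ± 10.9 in LD_20d, 70.1 ± 2.99 in SD_20d, 38.5 ± 10.1 in LD_40d and 84.2 ± 11.9 in SD_40d. As deposited it rose under SD at 40 days (1.13 ± 0.20, adjusted p = 0.0297) and differed by 0.40 ± 0.20 at 20 days (adjusted p = 0.329). In all 3 SD_20d and all 3 LD_40d libraries, its FPKM fits its count only with the total of the same-numbered library of the other group, which holds for 1 of 21144 genes at a tolerance of 0.01 reads. With those counts exchanged between the 2 groups, SD_20d had 37.6 ± 9.06 CPM and LD_40d had 71.6 ± 3.78, and SD minus LD was -0.50 ± 0.20 at 20 days (adjusted p = 0.215) and 0.23 ± 0.19 at 40 days (adjusted p = 0.604). Against the control, the changes as deposited and exchanged were 1.77 ± 0.21 and 0.87 ± 0.20 for SD at 20 days, and 0.90 ± 0.20 and 1.80 ± 0.20 for LD at 40 days, all 4 called. They were 1.37 ± 0.20 for LD at 20 days and 2.03 ± 0.21 for SD at 40 days as deposited. From 20 to 40 days, SOC1 differed by 0.26 ± 0.20 under SD as deposited (adjusted p = 0.298) and rose by 1.16 ± 0.20 exchanged (adjusted p = 9.9e-04); under LD it differed by -0.47 ± 0.20 and 0.43 ± 0.19 (adjusted p = 0.147 and 0.173).

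Across the 2 ages, 25 genes were called in the same direction, 6 up (0.0453 expected from the sizes of the lists; Fisher's exact test, p = 3.6e-12) and 19 down (0.347 expected, p = 5.4e-29), and 0 in opposite directions (0.0838 expected for up at 20 and down at 40 days, 0.188 for down and then up). The rises included CAB8, CAB37, LHCA4, POR1 and RFS6. The falls included RVE1, RVE7, COL9, PPCK1 LOC110038259, GA2OX8, PP2C06, CYP93G1, ATJ8 and, named after its values were seen, the early light-induced protein ELIP1 (LOC110024270, -1.57 and -2.01). Across all 16700 genes, which are not independent replicates, the fold changes at the 2 ages had Pearson r = 0.079 and Spearman rho = 0.127. The expected numbers and Fisher's exact test treat genes as independent too, although both comparisons come from the same fit. The number shared was 139 with DESeq2, 17 with a log2 change of at least 1 and 17 with the block. It was 14 and 9 without LD_20d replicates 1 and 3, 10 and 3 without SD_20d replicates 2 and 3, 0, 8 and 49 without LD_40d replicates 1, 2 and 3, and 139, 0 and 5 without SD_40d replicates 1, 2 and 3.

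The interaction asks whether the difference between SD and LD itself changed from 20 to 40 days. No gene passed with edgeR (0 genes; 1832 at an unadjusted p under 0.05), 33 passed with DESeq2 and 0 with limma-voom. The genes with the smallest p failed the correction at an adjusted p of 0.385. They included GHD7-like LOC110024148 (2.66 ± 0.49), AUR3 (-1.83 ± 0.33), EPFL6 (LOC110021258, -2.50 ± 0.53), a signal peptide of the family that patterns stomata, the aminotransferase AGT2 (LOC110021412, -2.39 ± 0.45), the helicase RH14 (LOC110028444, -1.28 ± 0.22) and the kinase MPK7 (LOC110019086, -3.34 ± 0.69). PEPC LOC110027447 (1.93 ± 0.90) and LOC110022615 (0.04 ± 0.17) did not pass (adjusted p = 0.456 and 0.942). GHD7-like transcript stood at 6.71 ± 2.03, 2.11 ± 0.0860, 12.0 ± 3.34 and 24.1 ± 9.51 CPM in LD_20d, SD_20d, LD_40d and SD_40d. As lists, 12 were called, and none of them held with an estimated correlation (adjusted p = 0.469 to 0.702 with an estimated correlation). Cell cycle (median -0.63, adjusted p = 3.2e-13), guard cell (median -0.63, adjusted p = 0.00586), cell wall (median -0.26, adjusted p = 0.0384) and ribosome genes (median -0.23, adjusted p = 2.5e-08) passed with a lower SD minus LD difference at 40 days. Clock (median 0.31, adjusted p = 0.0478), light signalling (median 0.14, adjusted p = 0.0391), photosystem (median 0.21, adjusted p = 0.00132), Calvin cycle (median 0.25, adjusted p = 0.00586) and CAM (median 0.19, adjusted p = 0.0149) passed with a higher one. So did heat shock (median 0.13, adjusted p = 0.0149), vascular (median 0.18, adjusted p = 0.03) and meristem genes (median 0.46, adjusted p = 0.0149). Clock and flowering-time genes numbered 0 up and 0 down of 29 and of 43 (0 up and 0 down, and 2 up and 0 down, when adjusted over the list alone). The count of genes was 8 without LD_20d replicate 2 and 1124 without SD_40d replicate 1, and that of lists 6 without LD_20d replicate 1 and 7 without SD_40d replicate 3.

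Against the control, photoperiod, temperature and age changed together, so these 4 comparisons describe the whole shift from the starting plants. Clock transcripts were among the genes that changed. In LD at 20 days, RVE7 rose by 7.95 ± 0.54, RVE1 by 5.46 ± 0.23, CDF1 (LOC110018623) by 4.87 ± 0.31 and LHY LOC110025280 by 2.73 ± 0.32, all genes with dawn maxima in textbook plant clocks. GI fell by 4.17 ± 0.36, from 628 ± 23.2 to 34.9 ± 8.04 CPM. The blue-light receptor Adagio-like protein 3 (LOC110037462) fell by 5.93 ± 0.44 and the pseudo-response regulators PRR95 (LOC110019887) and PRR73 (LOC110039462) by 3.46 ± 0.54 and 1.17 ± 0.19 (adjusted p of these 8 genes from 1.2e-08 to 9.3e-04). In SD at 20 days the same 8 genes changed by 4.56 ± 0.52, 3.58 ± 0.22, 4.20 ± 0.31, 2.71 ± 0.32, -5.27 ± 0.38, -5.12 ± 0.42, -3.38 ± 0.54 and -2.05 ± 0.20 (adjusted p = 8.9e-07 to 5.1e-04). Clock genes numbered 8 up and 10 down of 29 in LD (9 up and 10 down when adjusted over the list alone), and 10 up and 12 down in SD (the same numbers when adjusted over the list alone). Flowering-time genes numbered 11 up and 5 down of 43 in LD and 11 up and 9 down in SD (the same numbers when adjusted over the list alone).

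At 20 days more photosynthesis genes fell than rose against the control. Of 19 light-harvesting genes, 14 fell in LD (median -1.95, adjusted p = 4.5e-14) and 17 in SD (median -1.46, adjusted p = 1.8e-11), with 0 up in either (14 and 19 down when adjusted over the list alone). Neither this list nor any other at 20 days held with an estimated correlation (adjusted p = 0.318 to 0.711 in LD and 0.46 to 0.465 in SD with an estimated correlation). LHCA4 fell by 4.16 ± 0.23 and 3.07 ± 0.21. Photosystem genes fell in 30 of 54 cases in LD (median -0.70, adjusted p = 2.7e-10) and 38 in SD (median -1.04, adjusted p = 2.4e-12), with 2 and 1 up. Adjusted over the list alone they were 3 up and 33 down, and 3 up and 42 down. Without 11 ferredoxin-dependent enzymes of other pathways that the list holds, 27 of 43 fell and 1 rose in LD, and 30 fell and 0 rose in SD. The thylakoid term held 162 falls among its 326 genes in SD (adjusted p = 4.4e-37) and 90 in LD (adjusted p = 9.9e-11). Cell cycle genes rose in 41 of 175 cases in LD (median 0.24, adjusted p = 0.0142) and 78 in SD (median 0.60, adjusted p = 4.8e-08), with 9 and 7 down. Adjusted over the list alone they were 41 up and 10 down, and 81 up and 7 down. Without 8 inhibitors of cyclin-dependent kinases they were 40 up and 7 down of 167, and 77 up and 5 down. The rise in LD rested on its libraries unequally. Cell cycle scores were -0.20, 0.84 and 0.28 in LD_20d replicates 1, 2 and 3, beside -0.26 to 0.10 in the control, and without LD_20d replicate 2 the list cell_cycle_histones in LD at 20 days vs control did not pass (adjusted p = 0.306). CYCA1-3 (LOC110031192, 6.30 ± 1.41), a cyclin, and the kinesin KIN14C (LOC110034037, 1.71 ± 0.17) rose in SD. The cytoskeleton term held 121 rises among 278 genes in SD (adjusted p = 3.4e-19). SPL and AP2 genes, families of which some members act in the age pathway of flowering, also passed upward in LD (median 0.58, adjusted p = 0.00111, 10 up and 2 down of 31) and SD (median 0.73, adjusted p = 2.0e-04, 14 up and 1 down). They were 12 up and 2 down, and 19 up and 1 down, when adjusted over the list alone. Without 3 members that only share a name they were 10 up and 0 down of 28, and 14 up and 0 down. SPL12 (LOC110039299) rose by 1.34 ± 0.19 in SD.

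Further lists passed downward at 20 days. They were ethylene in LD (median -0.29, adjusted p = 0.0163) and SD (median -0.66, adjusted p = 0.00708), antioxidants in LD (median -0.17, adjusted p = 0.0449) and SD (median -0.33, adjusted p = 0.00838), and cytosolic ribosome in LD (median -0.24, adjusted p = 2.4e-07). In SD, chlorophyll synthesis (median -0.48, adjusted p = 0.00676) and the Calvin cycle (median -0.71, adjusted p = 6.2e-04) also passed downward. Light signalling (median 0.61, adjusted p = 4.7e-04) and auxin genes (median 0.40, adjusted p = 0.0163) passed upward in LD, and guard cell markers in SD (median 0.95, adjusted p = 0.0473). With an estimated correlation none of the 9 calls in either comparison held (adjusted p = 0.318 to 0.711 in LD and 0.46 to 0.465 in SD with an estimated correlation). In LD the starch-degrading BAM3 (5.75 ± 0.51), PPCK1 LOC110038259 (5.94 ± 0.80), SPA3 (3.31 ± 0.20) and the cambium regulator WOX4 (LOC110026126, 3.39 ± 0.71) rose, and so did DFR (LOC110022255, 1.58 ± 0.18) of anthocyanin synthesis. The ethylene response factor ERF109 (LOC110021501, -7.37 ± 1.75), pyruvate decarboxylase PDC4 (LOC110029946, -6.75 ± 1.45), an ascorbate oxidase homologue (LOC110033152, -6.61 ± 1.17) and BT1 LOC110022335 (-6.30 ± 1.12) fell in LD. So did caffeoylshikimate esterase (CSE, LOC110032551, -5.85 ± 0.54) of lignin synthesis, the defence regulator WRKY70 (LOC110036650, -5.17 ± 0.36), the chaperone DJC76 (LOC110018084, -4.65 ± 0.24), RFS6 (-3.38 ± 0.21) and the auxin response repressor IAA6 (LOC110021205, -1.85 ± 0.17) (adjusted p of these genes from 9.3e-08 to 0.00824). PEPC LOC110027447 fell by 2.50 ± 0.67 in LD (adjusted p = 0.0159; without LD_20d replicate 1 or 2 the call ended, at an adjusted p of up to 0.061) and by 3.68 ± 0.70 in SD. In SD, PDC4 (-7.61 ± 1.58), CSE (-6.61 ± 0.58), DJC76 (-5.94 ± 0.26) and the membrane fusion protein SYP121 (LOC110039157, -6.95 ± 0.71) fell; ERF109 was 230-fold lower (95% counting interval 78.3 to 1118), and GA2OX8 at least 62.0-fold lower. HSFB4 (LOC110036572, 6.44 ± 1.23), a heat stress factor, TDT (LOC110038403, 3.71 ± 0.60), which carries malate across the tonoplast, and CAO (LOC110035673, 1.38 ± 0.16), which makes chlorophyll b, rose in SD. SPA3 (2.28 ± 0.19), WOX4 (3.83 ± 0.71) and PP2C06 (3.41 ± 0.15) rose there too (adjusted p of these genes from 2.7e-08 to 0.00554). In all, 4002 genes were called in LD (1904 up, 2098 down) and 5864 in SD (2867 up, 2997 down), and 1675 and 2504 with a log2 change of at least 1.

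After 40 days the same clock genes were still called against the control. In LD, RVE7 rose by 8.54 ± 0.55, RVE1 by 5.99 ± 0.23, CDF1 by 5.73 ± 0.32 and LHY LOC110025280 by 3.93 ± 0.33, and GI fell by 4.42 ± 0.37. In SD the values were 5.63 ± 0.52, 4.70 ± 0.22, 5.94 ± 0.33, 4.87 ± 0.35 and -4.33 ± 0.36 (adjusted p of these genes from 4.4e-09 to 3.5e-06 in LD and from 5.0e-08 to 7.3e-06 in SD). Clock genes numbered 11 up and 9 down of 29 in LD and 9 up and 9 down in SD (11 up and 10 down, and 10 up and 10 down, when adjusted over the list alone). Flowering-time genes numbered 11 up and 5 down of 43 in LD and 13 up and 10 down in SD (11 up and 6 down, and 16 up and 10 down, when adjusted over the list alone); 1 of the 10 falls in SD was of an EH domain protein. PIL13 rose by 6.19 ± 0.41 in LD and 8.19 ± 0.45 in SD, from 3.82 ± 0.807 CPM in the control. In SD, the heat stress factor HSFB2B (LOC110027071, 7.03 ± 1.06), the mitochondrial heat shock protein HSP22 (LOC110021441, 6.60 ± 1.25) and AFP3 (LOC110036077, 7.31 ± 1.33), related to regulators of abscisic acid responses, rose. GHD7-like LOC110024148 rose there by 1.65 ± 0.34 (adjusted p = 0.00213), while in SD at 20 days it was called lower than in the control. AP2 (LOC110021827) rose by 1.66 ± 0.15, laccase LAC22 (LOC110030239) by 3.61 ± 0.40, CAO by 2.24 ± 0.17 and the carbonic anhydrase BCA2 (LOC110036198) by 1.51 ± 0.22 (adjusted p of these SD rises from 1.3e-07 to 0.00213).

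In LD at 40 days BAM3 (6.57 ± 0.52), PPCK1 LOC110038259 (6.55 ± 0.82), PP2C06 (4.98 ± 0.16), SPL12 (1.53 ± 0.19) and a knotted-1-like homeobox gene (LOC110024018, 1.14 ± 0.15) rose. CYP71A25 (LOC110023992, -5.75 ± 0.29), BT1 LOC110022335 (-5.47 ± 1.06), WRKY70 (-4.18 ± 0.34) and ORR10 LOC110034179 (-2.13 ± 0.21) fell (adjusted p = 1.3e-09 to 0.00216). In SD, MYB306 (LOC110025017, -6.34 ± 1.16), the cell wall protein PGL2 (LOC110038821, -5.17 ± 1.10) and RFS6 (-2.40 ± 0.20) fell (adjusted p = 3.8e-06 to 0.00273). PEPC LOC110027447 was at -1.62 ± 0.65 in LD and -0.87 ± 0.64 in SD and did not pass (adjusted p = 0.0795 and 0.299). PEPC LOC110022615 was called in none of the 4 comparisons with the control (0.04 ± 0.12 and -0.08 ± 0.12 in LD and SD at 20 days, -0.13 ± 0.12 and -0.20 ± 0.12 at 40 days, adjusted p of 0.201 or more). As lists, 13 were called in the 2 comparisons, and none of these calls held with an estimated correlation (adjusted p = 0.556 to 0.83 in LD and 0.603 to 0.774 in SD with an estimated correlation). Light harvesting in LD (median -1.63, adjusted p = 4.7e-09, 12 down and 0 up of 19) and SD (median -1.07, adjusted p = 2.4e-07, 15 down and 0 up; 12 and 16 down when adjusted over the list alone) passed downward. So did cell wall genes in LD (median -0.48, adjusted p = 0.00161) and SD (median -0.73, adjusted p = 3.7e-04) and cytosolic ribosome genes in LD (median -0.34, adjusted p = 7.8e-09) and SD (median -0.39, adjusted p = 1.4e-07). The same held for photosystem genes in LD (median -0.37, adjusted p = 0.0408), and ethylene (median -0.58, adjusted p = 0.044) and cell cycle genes (median -0.48, adjusted p = 0.041) in SD. Light signalling in LD (median 0.70, adjusted p = 3.8e-04) and SD (median 0.78, adjusted p = 6.3e-04) and meristem markers in LD (median 0.56, adjusted p = 0.0372) and SD (median 0.71, adjusted p = 0.0317) passed upward. Blue light response was over-represented among the rises in LD (25 of 60 genes, adjusted p = 6.8e-04), and ribosome among the falls in SD (96 of 233 genes, adjusted p = 2.9e-11). In all, 4599 genes were called in LD (2321 up, 2278 down) and 6399 in SD (3142 up, 3257 down), and 1712 and 2514 with a log2 change of at least 1.

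LD and SD moved largely the same genes away from the control. At 20 days 1479 genes rose in both (327 expected from the sizes of the lists) and 1755 fell in both (377 expected), with 2 in opposite directions; at 40 days the numbers were 1901 (437) and 1900 (444), with 0 in opposite directions. In 20 simulations all 15 libraries, the controls included, were drawn with no change between groups, and LD and SD shared the 3 simulated controls. Each simulated comparison gave 0 to 2 calls, never in LD and SD at once, so none could be shared. These counts are thus no measure for the overlap of calls. The simulated shared controls alone gave a Pearson r across genes of 0.508 at 20 days, against 0.875 observed. The covariance of the fold changes was 0.906 at 20 days and 0.737 at 40 days, against 0.0708 and 0.0709 in the simulations. Each gene was drawn independently, so differences that many genes of a real control library share are not in the simulated values. Called alike in all 4 comparisons were 753 rises and 957 falls. These held 7 rises and 9 falls among the 29 clock genes, 12 and 5 among the 38 light signalling genes, 0 and 10 among the 19 light-harvesting genes, and 0 and 16 among the 165 cytosolic ribosome genes. With a log2 change of at least 1 the numbers shared were 1340 at 20 days and 1321 at 40 days. Part of the excess over the expected numbers may come from the shared controls.

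From 20 to 40 days at constant conditions, more cell cycle genes fell than rose and more photosystem genes rose than fell in both photoperiods. Under SD, 111 of 175 cell cycle genes (109 of 167 without kinase inhibitors) fell and 4 rose (median -1.17, adjusted p = 1.7e-14; 6 up and 118 down when adjusted over the list alone). Neither this list nor any other under SD held with an estimated correlation (adjusted p = 0.532 with an estimated correlation for each). The topoisomerase TOP2 (LOC110022709), needed to part replicated chromosomes, fell from 143 ± 36.4 to 0.129 ± 0.0808 CPM, histone H2AX (LOC110024806) fell by 2.04 ± 0.25, and CYCA1-3 had no count in SD_40d and was at least 360-fold lower. LOC110033660, described as like an interactor of constitutively active ROP proteins, also had no count in SD_40d and was at least 251-fold lower. EPFL6 fell by 3.51 ± 0.40 and the cell wall invertase CIN3 (LOC110025305) by 3.48 ± 0.43, among the smallest adjusted p in the comparison (6.5e-04). Photosystem genes rose in 31 of 54 cases and fell in 2 (median 0.70, adjusted p = 3.0e-08; 34 up and 2 down when adjusted over the list alone), and without the 11 enzymes of other pathways 23 of 43 rose and 1 fell. The Calvin cycle enzyme GAPB (LOC110034978, 1.46 ± 0.22), BCA2 (1.68 ± 0.22), COP1 (LOC110022462, 1.35 ± 0.18), ZEP (LOC110039065, 1.19 ± 0.17) of xanthophyll and abscisic acid synthesis, HSFC1 (2.84 ± 0.36) and SPL1 (LOC110027702, 1.0 ± 0.15) rose. GHD7-like LOC110024148 rose by 3.50 ± 0.37, CDF2 LOC110019467 by 2.15 ± 0.26, LHY LOC110025280 by 2.16 ± 0.31, CDF1 by 1.75 ± 0.26, RVE1 by 1.12 ± 0.18 and PEPC LOC110027447 by 2.81 ± 0.68. VIL2 (LOC110037314), of a family acting in vernalization, fell by 2.40 ± 0.38 (adjusted p of these 7 genes from 6.5e-04 to 0.00582). Clock genes numbered 14 up and 2 down of 29 (the same when adjusted over the list alone; median 0.47, adjusted p = 0.0231), and flowering-time genes 11 up and 8 down of 43 (the same when adjusted over the list alone). Among these 8 falls 2 were of EH domain proteins, which only share letters with a flowering-time gene, and without such members it was 11 up and 6 down of 39. PEPC LOC110022615 was not called (-0.12 ± 0.12, adjusted p = 0.429). The transporter ABCG6 (LOC110038628, 6.74 ± 1.24) rose, and the esterase LOC110029328 was 244-fold higher (95% counting interval 67.1 to 2019).

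Other lists that passed under SD between the ages were chlorophyll synthesis (median 0.56, adjusted p = 7.7e-04), the Calvin cycle (median 0.29, adjusted p = 0.00114), sugars and starch (median 0.21, adjusted p = 0.0429), heat shock (median 0.23, adjusted p = 0.0195) and meristem markers (median 0.56, adjusted p = 0.0264), all upward. Downward lists were SPL and AP2 (median -0.56, adjusted p = 0.024), cell wall (median -0.46, adjusted p = 7.7e-04), ribosome (median -0.31, adjusted p = 1.7e-06) and guard cell markers (median -1.13, adjusted p = 0.00522). None of the 12 held with an estimated correlation (adjusted p = 0.532 with an estimated correlation for each). In all, 6801 genes were called under SD (3350 up, 3451 down; 2936 with a log2 change of at least 1).

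Under LD, 22 of 175 cell cycle genes fell from 20 to 40 days and 1 rose (median -0.51, adjusted p = 1.8e-08; 3 up and 52 down when adjusted over the list alone). Neither this list nor any other under LD held with an estimated correlation (adjusted p = 0.6 to 0.711 with an estimated correlation). Photosystem genes rose in 4 of 54 cases and fell in 0 (17 up and 1 down when adjusted over the list alone), and in 3 of 43 cases without the 11 enzymes of other pathways. Clock genes numbered 1 up and 0 down of 29 (the same when adjusted over the list alone), and flowering-time genes 1 up and 1 down of 43 (4 up and 1 down when adjusted over the list alone). KNOLLE (LOC110033252, -6.98 ± 1.47), a syntaxin of cell plate formation, fell; the kinesin KIN10C (LOC110022016) was 140-fold lower (95% counting interval 47.5 to 680), UBC20 (LOC110031304) 142-fold (38.8 to 1174) and an early nodulin-like protein (LOC110029845) 161-fold (44.2 to 1334). WOX4 (-3.31 ± 0.70), XTH32 (LOC110017913, -2.64 ± 0.42), a xyloglucan-modifying enzyme, CIN3 (-2.35 ± 0.42), ORR10 LOC110035490 (-2.01 ± 0.29), PPCK1 LOC110023763 (-1.60 ± 0.30) and VIL2 (-1.51 ± 0.37) fell. HSP22 (4.90 ± 1.29), WRKY46 (LOC110021306, 3.78 ± 0.85), NUDT4 (LOC110028568, 3.75 ± 0.86) and the ascorbate oxidase homologue LOC110033152 (4.82 ± 1.12) rose. CDF2 LOC110019467 (1.39 ± 0.25), LHY LOC110025280 (1.20 ± 0.30), the gibberellin receptor GID1C (LOC110030604, 0.98 ± 0.17), RPE (LOC110028925, 0.82 ± 0.20) of the Calvin cycle, COP1 (0.75 ± 0.18) and PSAF (LOC110029064, 0.73 ± 0.14) of photosystem I rose as well (adjusted p of all these genes from 0.0178 to 0.0467). PEPC LOC110027447 (0.88 ± 0.64) and LOC110022615 (-0.16 ± 0.12) were not called (adjusted p = 0.399 and 0.396). Upward lists were photosystem (median 0.37, adjusted p = 1.8e-08), light harvesting (median 0.31, adjusted p = 0.0357), chlorophyll synthesis (median 0.40, adjusted p = 4.7e-04), the Calvin cycle (median 0.32, adjusted p = 0.00868) and sugars and starch (median 0.17, adjusted p = 0.0382). Downward lists besides the cell cycle were SPL and AP2 (median -0.29, adjusted p = 0.0206), auxin (median -0.30, adjusted p = 0.00868), flavonoids (median -0.25, adjusted p = 0.0206) and the cell wall (median -0.32, adjusted p = 0.00107). In all, 861 genes were called under LD (362 up, 499 down, so 42.0% up). The count was 2226 with DESeq2, 483 with limma-voom, 146 in a fit to these 6 libraries, 301 with the block and 493 with a log2 change of at least 1. It was 2 and 16 without LD_20d replicates 2 and 3 and 1, 327 and 2027 without LD_40d replicates 1, 2 and 3. The balance of directions moved both ways, with 33.6% and 31.3% up without LD_20d replicates 1 and 3 and 78.3% and 50.3% up without LD_40d replicates 2 and 3. Of the 20 called genes named here, 0 kept their call in every such fit, and 5 lists passed without LD_40d replicate 1.

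**Figure D3:**
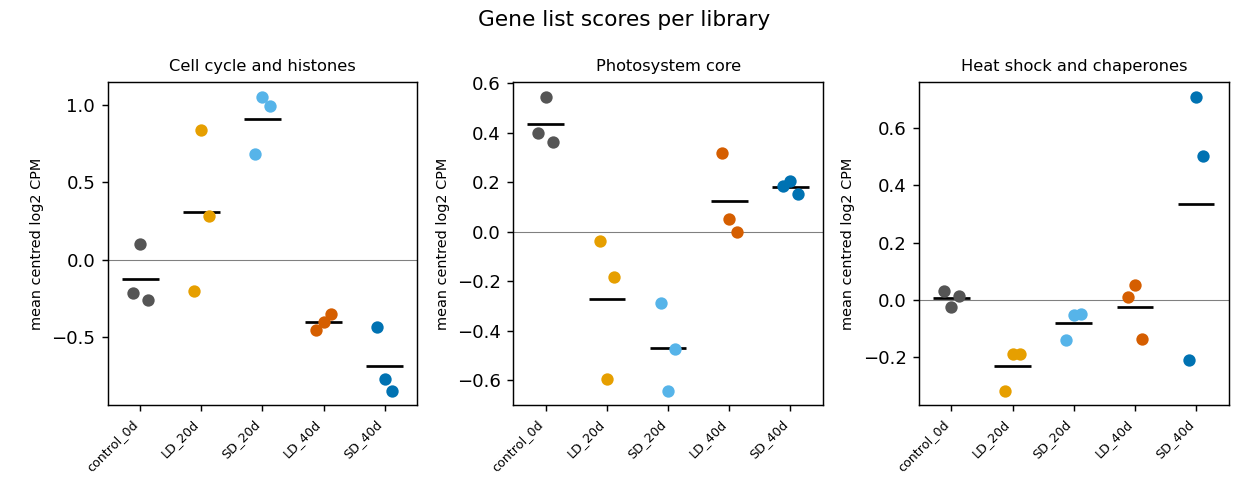
Mean centred log2 CPM of the members of 3 gene lists in each library (points), with the group mean (line); the lists hold 175, 54 and 154 genes. Cell cycle scores are highest in SD_20d (0.68 to 1.05) and below 0 in all 40-day libraries, photosystem scores are highest in the control (0.36 to 0.54), and SD_40d replicate 1 (-0.21) lies apart from replicates 2 and 3 (0.71 and 0.50) in heat shock genes.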

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

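The tests of explanations in this part were chosen only after the results were seen, and the count of other splits of the libraries was planned.

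The difference between SD and LD itself differed between 20 and 40 days for 12 gene lists, by a test of that difference with a preset correlation. Cell cycle and histone genes (median log2 difference -0.63), guard cell markers (-0.63), cell wall genes (-0.26) and cytosolic ribosome genes (-0.23) stood lower in SD relative to LD at 40 than at 20 days. Clock genes (0.31), light signalling genes (0.14), photosystem genes (0.21), Calvin cycle genes (0.25), CAM genes (0.19), heat shock genes (0.13), vascular markers (0.18) and meristem markers (0.46) stood higher. None of the 12 held with an estimated correlation (adjusted p = 0.469 to 0.702). Among single genes, edgeR called 0 in the interaction (1832 at an unadjusted p under 0.05), DESeq2 called 33 and limma-voom 0. Of 100 splits of the 12 libraries, the real one included, 100 gave as many calls as the real one or more, with 7984 at the highest. With 0 calls in the real one this holds by construction, so the count of splits decides nothing about chance.

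SD_40d replicate 1 lay at -16.9 on the first principal component, beside -77.6 and -89.3 for replicates 2 and 3, and without it 1124 genes passed the interaction and 2025 differed between SD and LD at 40 days. A long-photoperiod library under a short-photoperiod label is argued against by the 144 genes called between SD and LD at 20 days, but not by all values. On these genes SD_40d replicate 1 scored -0.0383 (position 1.05, with LD_40d at 0 and replicates 2 and 3 at 1). Replicates 2 and 3 scored -0.0621 and -0.0796, LD_40d -0.830 to -0.555 and LD_20d replicate 2 -0.139. Across all genes tested, SD_40d replicate 1 correlated more with LD_40d replicates 1, 2 and 3 (r = 0.960, 0.969 and 0.976) than with SD_40d replicates 2 and 3 (0.948 and 0.936). Whether SD_40d replicate 1 carries the right label stays open. Library size is argued against, since its total of 13663222 counts (13.7 M) lies inside the range of the other 14 libraries. Another stage of leaf development is left open. The difference of replicates 2 and 3 from replicate 1 followed the change from 20 to 40 days under LD. The Pearson r was 0.405 across genes, which are not independent replicates. Replicate 1 was flagged on the first principal component, which itself ran from the 20-day to the 40-day libraries. A positive r was thus likely beforehand. The LD_40d libraries lay at -59.8 to -18.6 on that component. A library of that group under the wrong label could thus give such an r too, and the r favours neither reading. The stage of each leaf is not recorded, so leaf stage stays a hypothesis, and a biological difference between the plants was not tested otherwise.

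SOC1 (LOC110020085) has counts and FPKM that fit the total of the same-numbered library of the other group in 6 libraries, those of SD_20d and LD_40d, and rounding is argued against, since 0 other genes were off by more than 0.01 reads. An exchange of this gene's values between the groups may explain it: library totals implied by the FPKM of other genes differ from the sums of counts by -341, -456 and -503 in SD_20d and by 341, 456 and 503 in LD_40d, for replicates 1, 2 and 3, and by 0 in the other libraries. The reverse, with SOC1 in place and all other genes exchanged, cannot be told apart by this check, which does not say which values moved, and it would make the contrast of photoperiods and the contrast of ages trade places. Clock, light signalling and flowering-time genes were over-represented among the calls between SD and LD as labelled (12 of 110 genes, 1.29 expected, odds ratio 10.9, 95% interval 5.36 to 20.4; Fisher's exact test, p = 6.3e-09). Between 40 and 20 days the association was weaker (51 called, 45.3 expected, odds ratio 1.23, 95% interval 0.831 to 1.83; Fisher's exact test, p = 0.286), and without 7 genes that only share letters with these lists the odds ratios were 11.8 and 1.30. SOC1 itself, called between SD and LD only with its counts as deposited, is among the 12. The 2 contrasts also differ in size, with 196 and 6882 genes called. These ratios therefore do not decide which values moved.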

How the results depend on the processing

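Robust dispersions, lists without name mismatches, SOC1 exchanged and the added terms were tests chosen only after the results were seen; the other alternatives were planned. Genes named in the report and called against the control or under SD between ages kept their calls with each library left out, except PEPC LOC110027447 in LD at 20 days. AGL65 (LOC110024229) lost its call in SD against the control with any of 6 libraries left out at 20 days, and at 40 days with any but SD_40d replicate 1. Of 247 values of named genes, 22 lost their call with the replicate block; of 242, 19 gained one with DESeq2. SD against LD at 20 days gave 144 calls, 825 with DESeq2, 78 with a log2 change of at least 1 and 5 (without SD_20d replicate 3) to 892 (without LD_20d replicate 2) with a library left out. At 40 days 77 became 614 with DESeq2, 0 with only the groups compared (by edgeR, 1614 unadjusted), 45 with the replicate block and 0 (without LD_40d replicate 1 or SD_40d replicate 2) to 2025 (without SD_40d replicate 1) with a library left out. LD at 40 against 20 days gave 861, and 2226 with DESeq2, 483 with limma-voom, 146 with only the groups compared, 301 with the block, 493 with a log2 change of at least 1 and 1 (without LD_40d replicate 1) to 2027 (without LD_40d replicate 3) with a library left out. A log2 change of at least 1, a narrower criterion by construction, left 1675 and 2504 calls in LD and SD against the control at 20 days, 1712 and 2514 at 40 days and 2936 in SD at 40 against 20 days. The interaction gave 33 with DESeq2 and 0 to 1124 (without SD_40d replicate 1) with a library left out. Lists past the threshold fell from 79 to 0 with an estimated correlation, in each of the 9 comparisons. With a library left out they were 6 to 15 (11) at 20 days, 2 to 6 (3) at 40 days, 5 to 12 (10) in LD between ages and 6 to 12 (12) in the interaction. The 25 photoperiod calls shared by the ages became 139 with DESeq2 and 0 to 139 with a library left out; those shared against the control became 1340 of 3234 at 20 days and 1321 of 3801 at 40 days with a log2 change of at least 1. Directions reversed in uncalled genes: LHY LOC110025280 at 20 days (-0.28 to 0.15), PEPC LOC110022615 (-0.15 to 0.045) and GI (LOC110019219, -0.20 to 0.46) at 40 days, and PEPC LOC110022615 in LD at 20 days vs control (-0.024 to 0.082) and in the interaction (-0.031 to 0.16), with a library left out. SOC1 (LOC110020085) exchanged reversed as well, to -0.50 in SD against LD at 20 days and to 0.43 in LD between ages. Save where the construction shows it, the cause was not tested. Scaling, filters and robust dispersions left each count of calls within 1.5 times, and no scaling moved the median of all genes by over 0.1. Genes of fewer counts were recovered less often in simulation: of those changed 2-fold at 20 days, 14 of 53 below the median CPM of the changed genes (20.1) and 36 of 47 at or above it, a split chosen after the results were seen.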

Other observations

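The tests on clock genes, on changes shared by the photoperiods, on terms between ages and on lists with genes at 0, and those of AGL65 with a library left out, were chosen only after the results were seen; the counts of other splits were planned.

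Genes classed as dawn genes, among them CDF loci of the flowering-time list, stood mostly higher than in the control, and those classed as evening genes lower. This was so for 21 of 27 genes in LD and 21 in SD at 20 days, and for 22 in LD and 20 in SD at 40 days (17 dawn and 10 evening genes, called or not). In the same order, dawn genes called the other way, down, numbered 2, 3, 2 and 2, beside 12 called up in each comparison. Evening genes called up numbered 0, 2, 2 and 1, beside 7, 7, 6 and 6 called down. LNK2 LOC110028431 and RVE7L (LOC110021779), classed as dawn genes, were called down in all 4 comparisons. The evening class includes PRR73 (LOC110039462) and PRR95 (LOC110019887 and LOC110033028), whose textbook maxima lie earlier in the day. These counts and the clock index below were not run without these PRR loci or without the CDF loci. A higher share of dividing tissue is argued against, since the 7 treated libraries with cell cycle scores no higher than the controls had clock indices (mean of dawn minus evening genes, log2) of 0.55 or more. That is 3.27 above the highest control (-2.73; control range 0.43). Of these libraries, only LD_20d replicate 1 (cell cycle score -0.205, clock index 0.959) lay inside the control range of scores (-0.262 to 0.0988). The others, all at 40 days, scored -0.845 to -0.350, below the controls. A comparison at an equal share thus rests on that library alone. Another hour of harvest than in the control could give this pattern. The fewest genes that moved that way were 20 of 27, under a mark of 4 in 5 that was set after the results were seen. With the hour not recorded, reaching that mark could not have shown another hour, so missing it is no evidence against one. Nor can another hour be told apart from an effect of the new light and temperature, because each treated library differs from the control in these too.

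From 20 to 40 days many of the same genes changed in both photoperiods. Genes called in the same direction under LD and SD numbered 779, of which 306 rose (72.6 expected; Fisher's exact test, p = 9.8e-158) and 473 fell (103 expected, p = 1.9e-295), and 1 gene was called in opposite directions. Across genes, which are not independent replicates, the changes had Pearson r = 0.807 and Spearman rho = 0.780. Fisher's exact test and the expected numbers treat genes as independent too, although both comparisons come from the same fit. This overlap was not run with a library left out, while the 861 LD calls it draws on changed strongly with single libraries, as given above. Among terms, DNA replication (60 of 103 genes, adjusted p = 1.2e-12) was over-represented among the falls under SD and chloroplast stroma among the rises under SD (196 of 496, adjusted p = 6.6e-20) and LD (37 of 496, adjusted p = 1.5e-06).

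Lists that passed in none of the 9 comparisons, with their lowest adjusted p, were flowering time (0.145), gibberellin (0.143), cytokinin (0.0579), abscisic acid (0.0995), jasmonate (0.165), cold and dehydration (0.108), defence (0.131), cuticle and epidermis (0.0825), and retroelements and viruses (0.132). Without members that only share a name, cytokinin passed in SD between ages (adjusted p = 0.0141) and cold and dehydration in SD at 20 days against the control (adjusted p = 0.0404), with the preset correlation; these were not run with an estimated correlation. Of the 11 genes of the floral organ MADS list, 1 had enough counts to test, and it is AGL65 (LOC110024229), which shares letters with AGL6 and is no organ identity gene. It rose against the control in SD at 20 days (0.73 ± 0.25, adjusted p = 0.0401) and at 40 days (0.76 ± 0.25, adjusted p = 0.0304), and it was named after its values were seen. Neither call was stable: at 20 days it ended with any of 6 libraries left out (adjusted p up to 0.106), and at 40 days with any but SD_40d replicate 1 (adjusted p up to 0.144). Setting genes at 0 in a whole group to their bounds changed a list's median by at most 0.105. Response to chitin (41 of 88 genes, adjusted p = 1.2e-11) was over-represented among the falls in LD at 20 days against the control.

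The 6 libraries of each comparison can be split in 10 ways, too few for a share under 0.05. By edgeR, the real split of SD against LD at 20 days gave 144 calls and the highest other 0 (128 to 2243 genes at an unadjusted p under 0.05 in the other splits). At 40 days the real split gave 77 and the highest other 343, and 3 splits gave 77 or more. The splits with 343 and 262 calls keep SD_40d replicates 2 and 3 together, and so does another with 5 calls. The cause was not tested. In LD and SD against the control at 20 days the real splits gave 4002 and 5864 calls and the highest others 0 and 0 (487 to 1536 and 228 to 1482 unadjusted). At 40 days they gave 4599 and 6399, and the highest others 0 (280 to 1519 unadjusted) and 3. Between ages they gave 861 in LD and 6801 in SD, and the highest others 0 and 0 (285 to 2798 and 102 to 3639 unadjusted). Except in SD against LD at 40 days, 1 split, the real one, gave as many calls. Other tools were not run on these splits.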
